A study of Bos taurus with 8 samples.

How the data were processed

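Gene expression was measured in peripheral blood mononuclear cells, the blood fraction that holds lymphocytes and monocytes, from 3 groups of cows: lame crossbred, normal crossbred and normal Tharparkar, an Indian zebu breed. Total RNA was labelled with Cy3 and hybridised to 8 arrays of a 1-colour Agilent bovine design: 4 of the lame group, 2 of the normal crossbred group and 2 of the normal Tharparkar group. Per the labels' protocols, RNA samples were run as technical duplicates. The titles of the lame arrays carry 2 numbers (R1_1, R1_2, R2_1 and R2_2) and those of the normal arrays carry 1 (R1 and R2). Nothing in the labels says whether an RNA sample came from 1 cow or from a pool. The arrays lay on 2 slides, each of which held arrays of all 3 groups: slide 1 held lame R1_1 and R2_1 and the R1 array of each normal group, and slide 2 held the other 4.

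Each array's file held the intensity of every spot, as the authors deposited it from the scanner software. The processed signal was background-subtracted and detrended within the array, and no scaling between arrays had been applied, per the file headers. The headers name Agilent Feature Extraction 12.0.3.1, whereas the submitters' processing notes name Agilent Feature Extraction 11.5.1.1, and nothing settles which version the authors used for their own table. Flags for spots well above background, saturated or non-uniform came from the same files. The authors also deposited a table of log2 values whose scale and centring are not stated. Each of its columns followed the processed signal on the log2 scale, minus the array's 75th percentile and minus the probe's median over the 8 arrays, with a correlation above 0.99999. The column medians were 0.00 for lame R1_1, 0.00 for lame R2_1, -0.13 for lame R1_2, 0.88 for lame R2_2, -0.07 and -0.12 for the normal crossbred arrays and 0.03 and 0.09 for the normal Tharparkar arrays. A higher value in that table therefore means a brighter spot, and it served as an alternative.

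Values were computed here as log2 of the processed signal minus the array's 75th percentile over the 43653 noncontrol probes, with spots of a probe averaged. Control spots were left out, as were 35 probes that the scanner software marked as outliers on an array, and 0 spots were saturated. A probe was kept when it was well above background on every array of at least 1 group. Probes were named by matching their accession, without its version, to a RefSeq gene table of assembly ARS-UCD2.0: 27054 matched 1 gene, 26629 of them a gene with a named symbol, and 16599 kept the name in the file. The array annotation was made on the older bosTau6 assembly, so no coordinates were used, and the table served only for names and for which genes are neighbours. Each gene was represented by the probe with the highest mean, which gave 15137 genes.

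Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) in 1 fit with 3 group means, no covariates, 5 residual and 2.34 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Arrays were the observations, because the titles do not settle which arrays share an RNA sample. Arrays of a group include technical duplicates, so these p-values measure the spread between arrays and are too small as tests of cows. Each comparison was therefore refitted with duplicates averaged. That fit has 4 observations, 1 residual degree of freedom, which comes from the lame group, and an infinite prior, so every gene has the same variance and a call depends on the size of the fold change alone. Where a probe was well above background on every array of 1 group and on no array of the other, a lower bound of the fold difference is given. It sets the mean of the brighter group against the mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

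27 gene lists were fixed before the data were examined, as were the design, the named-gene rule and most alternatives. They cover type I interferon response, inflammatory cytokines and chemokines, the NF-kB pathway, pattern recognition receptors, MHC class I and class II antigen presentation, heat shock proteins, immediate early and activation genes, cell cycle, matrix remodelling, apoptosis, oxidative phosphorylation, ribosomal proteins, glycolysis and hypoxia, glucocorticoid response and the unfolded protein response. The remaining lists hold markers of granulocytes, monocytes, dendritic cells, T cells, gamma-delta T cells, NK and cytotoxic cells, B cells, plasma cells, erythroid cells, platelets and epithelia. Of 1101 list entries, 770 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison, and again with the correlation estimated. The list p-values rest on the same arrays, so they too are too small as tests of cows. A call lost with the estimated correlation need not reflect a high correlation. That of the interferon list in lame against normal crossbred was -0.015, and its call was lost. Limma's fry was an alternative test.

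Named genes carry a symbol, passed the test, were well above background on every array of both groups, and had every array of 1 group above every array of the other. Of these, the 8 highest and the 8 lowest were taken, plus up to 3 members of each list, up to 3 bounds per direction and up to 6 genes per direction that passed against both normal groups. A list with no such gene may give its member with the largest difference as a value only. Some genes that meet the rule are not reported here. ACTB, GAPDH, B2M and PTPRC served as reference genes.

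The steps were tested on simulated arrays with the real genes' means and array spread, with 200 of 15137 genes changed in 1 group. A log2 change of 2 was recovered for 80.5% of changed genes in lame against normal crossbred, for 81.5% in normal crossbred against normal Tharparkar and for 80.5% or 87.5% in lame against normal Tharparkar, depending on the group changed, with 10 to 12 false calls. A log2 change of 1 was recovered for 0% of changed genes in each comparison, so genes not called may still differ by 2-fold. With only 200 genes changed, the adjusted cutoff was stricter than in the data, so this share does not measure the sensitivity there. In lame against normal crossbred, for example, 816 of 1455 calls reached 2-fold and the others were smaller. In a simulation of lists, the 1 shifted list was called and 0 of 26 unshifted lists were. Its genes and arrays were drawn independently, so it cannot show how lists behave whose genes vary together. The inflammatory list, for example, had an estimated correlation of 0.127 in lame against normal crossbred. Unchanged groups were simulated 100 times with the array spread alone, and 100 times with a spread between RNA samples added, taken for each gene from the difference between the lame R1 and lame R2 arrays.

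Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' deposited table, other filters, the mean of a gene's probes, duplicates averaged by either number of the titles, replicate and slide blocks, array weights, fits on the 2 groups compared, other thresholds and each array left out. Fits on each lame RNA sample, on the 4 RNA samples as groups, and on quantile-normalized values with duplicates averaged were added after seeing the data. Normexp used the median spot signal, because the mean spot signal it was planned on was not among the columns. The number of arrays, 8 from 4 RNA samples, limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.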

Results

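The 8 arrays measured between 52.8% and 61.5% of the 43653 probes well above background, except lame R2_2 with 70.9%. That array was also brighter, with a median raw signal of 192.5 against 74 to 102 on the others, and a median raw signal of its negative control spots of 107 against 53 to 65. Gene-level values correlated across genes at 0.995 between the lame R1 arrays and at 0.981 between the lame R2 arrays. Arrays of the same normal group correlated at 0.995 to 0.997. Other pairs of lame arrays correlated at 0.951 to 0.970 and arrays of different groups at 0.931 to 0.966. The arrays therefore read as 4 RNA samples in duplicate: lame R1, lame R2, 1 normal crossbred and 1 normal Tharparkar. This reading is weaker for lame R2, whose 0.981 lay between the 0.970 of other lame pairs and the 0.995 of normal duplicates. The median SD between duplicates was 0.13 on the log2 scale and that between lame R1 and lame R2 was 0.35. In the following, n counts arrays: n = 4 arrays of 2 RNA samples in the lame group and n = 2 arrays of 1 RNA sample in each normal group.

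The first comparison, of lame with normal crossbred cows, addresses what differs with lameness within the crossbred type. The inflammatory cytokines IL1A and IL1B, which encode interleukin-1, were among the genes that fell furthest. IL1A was 16.3-fold lower in the lame arrays (log2 fold change -4.03, SE 0.48, adjusted p = 0.0036) and IL1B 11.2-fold lower (-3.49, SE 0.27, adjusted p = 0.00073). Other lower genes were CXCR1, a receptor for interleukin-8 (-3.82, SE 0.61), and TGM3, a transglutaminase (-2.95, SE 0.13), both members of the granulocyte list. PLAUR, the urokinase receptor (-2.91, SE 0.35), and DGAT2, an enzyme of triglyceride synthesis (-2.96, SE 0.25), fell too. Against these lower genes, TNFAIP6, a hyaluronan-binding protein induced by tumour necrosis factor, was 10.2-fold higher (3.35, SE 0.16), and CRYGS, a crystallin, 26.6-fold higher (4.73, SE 0.22). LYPD8 (2.82, SE 0.14), PPP1R1B (2.72, SE 0.54), SFXN1 (2.41, SE 0.42) and PRSS57 (3.49, SE 0.51) were higher too, as was CORO1B (5.17, SE 0.17), of which another probe gave 1.04. TNFAIP6 (-3.26) and PRSS57 (-4.48) were also lower in the normal crossbred than in the Tharparkar arrays. Their rise here cannot be told apart from a trait of the 1 normal crossbred RNA sample. VAT1L (-2.89, SE 0.21) and LSR (-2.81, SE 0.24) were lower.

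Genes that cells switch on within minutes of a stimulus were lower in the lame arrays. Of 35 measured members of the immediate early list, 16 fell and 0 rose (23 fell adjusted over the list alone), with a median log2 fold change of -0.74 (camera, adjusted p = 2.7e-09). This was the list call that held with an estimated correlation (adjusted p = 0.0181 with an estimated correlation). The transcription factors FOSB (-2.68, SE 0.15) and EGR1 (-2.36, SE 0.14) and the kinase SGK1 (-2.29, SE 0.15) fell most among its members. With slide as a block, which leaves the median unchanged in this balanced layout, adjusted p was 5.35e-09, and the median was -0.71 within either slide. The slides hold duplicates of the same RNA samples, so medians within slides, here and below, show technical agreement and say nothing about other cows. List p-values, here and below, are likewise too small as tests of cows. Of 28 inflammatory cytokines and chemokines, 11 fell and 1, TNFAIP6, rose (15 and 2 adjusted over the list alone). Their median was -0.83 (adjusted p = 0.00052, and adjusted p = 0.322 with an estimated correlation), with -0.77 within slide 1 and -0.82 within slide 2. Of 30 interferon response genes, 8 fell (13 fell and 1 rose adjusted over the list alone; median -0.52, adjusted p = 0.000146, and adjusted p = 0.0645 with an estimated correlation). IFIT3 (-2.08, SE 0.30), RTP4 (-1.29, SE 0.21) and OAS1Z (-1.18, SE 0.15) were among them.

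T cell and NK markers were lower than in the normal crossbred arrays and several monocyte markers higher. Against the Tharparkar arrays the T cell median was 0.42 and the NK median 0.34. The lower T cell and NK values therefore hold only against the 1 normal crossbred RNA sample. Of 31 T cell markers, 12 fell and 0 rose (17 adjusted over the list alone; median -0.59, adjusted p = 1.3e-06, and adjusted p = 0.156 with an estimated correlation), CD8A (-1.37, SE 0.13) and GATA3 (-1.08, SE 0.24) among them. The T cell median was -0.61 within slide 1 and -0.59 within slide 2. Of 21 NK and cytotoxic markers, 7 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.75, adjusted p = 0.0012, and adjusted p = 0.322 with an estimated correlation), including NKG7 (-1.44, SE 0.12), NCR3 (-1.28, SE 0.21) and FASLG (-1.17, SE 0.14). Of 29 monocyte markers, 5 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.39, with 0.22 for lame R1 and 0.36 for lame R2, adjusted p = 0.0039, and adjusted p = 0.322 with an estimated correlation). The complement genes C1QB (1.55, SE 0.15) and C1QC (1.38, SE 0.23) rose, whereas CD14 (-1.56, SE 0.31), the lipopolysaccharide co-receptor, fell, as did TLR4 (-1.71, SE 0.35), its partner in that response.

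Of 50 cell cycle genes, 7 fell and 0 rose (20 adjusted over the list alone; median -0.52, adjusted p = 2.2e-07, and adjusted p = 0.322 with an estimated correlation), including BIRC5 (-1.25, SE 0.15) and CDK1 (-1.20, SE 0.24). Of 21 glucocorticoid response genes, 6 fell and 1 rose (7 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.0421, and adjusted p = 0.234 with an estimated correlation); CXCR4 (-1.81, SE 0.13) and MT1A (-1.28, SE 0.24) fell. This call was lost with the mean of a gene's probes (median -0.18, adjusted p = 0.114), with quantile normalization (-0.27, 0.143), with duplicates averaged by the last number (0.0728), and without lame R1_1 (0.0724). It was also lost without lame R1_2 (0.0658) and without normal crossbred R1 (0.0526). Of 24 erythroid markers, 2 rose, KLF1 (0.93, SE 0.17) and BLVRB (0.69, SE 0.16), also adjusted over the list alone (median 0.37, adjusted p = 0.0049, and adjusted p = 0.168 with an estimated correlation; adjusted p = 0.066 with quantile normalization). Granulocyte markers did not pass as a list (median -0.24, adjusted p = 0.0568), although 8 of 30 fell and 1 rose (12 and 4 adjusted over the list alone), TCN1 (-2.31, SE 0.15) among them. Their median was -0.89 for lame R1 and -0.10 for lame R2, and -0.50 without lame R2_2.

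The other lists were not called in this comparison. The median was -0.96 for gamma-delta T cell markers (adjusted p = 0.0553), -0.28 for plasma cell markers (0.13), 0.15 for B cell markers (0.335), 0.23 for dendritic cell markers (0.538), 0.16 for platelet markers (0.475) and 0.47 for keratins and epithelial markers (0.118). It was 0.43 for matrix genes (0.475), where 5 rose and 6 fell, 0.22 for pattern recognition receptors (0.194), -0.09 for the NF-kB pathway (0.854), -0.05 for MHC class I (0.981) and 0.03 for MHC class II (0.854). It was 0.02 for heat shock proteins (0.691), -0.10 for apoptosis (0.538), -0.02 for oxidative phosphorylation (0.991), 0.06 for ribosomal proteins (0.118), 0.08 for glycolysis and hypoxia (0.755) and -0.22 for the unfolded protein response (0.123). The median and mean differed in sign for MHC class II (mean -0.74, and 0.04 without BOLA-DQA5, which was not well above background in the lame arrays), the NF-kB pathway (0.03) and heat shock proteins (-0.02), and the test of oxidative phosphorylation pointed up against a negative median and mean. Without lame R2_2 the median was 0.15 for matrix genes, 0.12 for dendritic cell markers, 0.29 for epithelial markers, 0.17 for ribosomal proteins, 0.14 for heat shock proteins and 0.12 for glycolysis and hypoxia. It was then -0.05 for apoptosis, -0.06 for the NF-kB pathway, -0.12 for MHC class I and 0.07 for MHC class II, and it turned to 0.08 for oxidative phosphorylation. Lame R1 minus lame R2 had a median of -0.65 for platelet markers, 0.26 for B cell markers and 0.26 for glycolysis and hypoxia. This difference was 0.37 for heat shock proteins, 0.60 for ribosomal proteins and 0.63 for oxidative phosphorylation. For each of these lists it exceeded in size the median over all lame arrays, which therefore does not describe both RNA samples. Of the reference genes, ACTB (0.15, SE 0.21), GAPDH (-0.15, SE 0.16), B2M (-0.25, SE 0.17) and PTPRC (-0.45, SE 0.13) did not pass the test, and the sign of ACTB and GAPDH turned with the mean of a gene's probes.

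**Figure D1:**
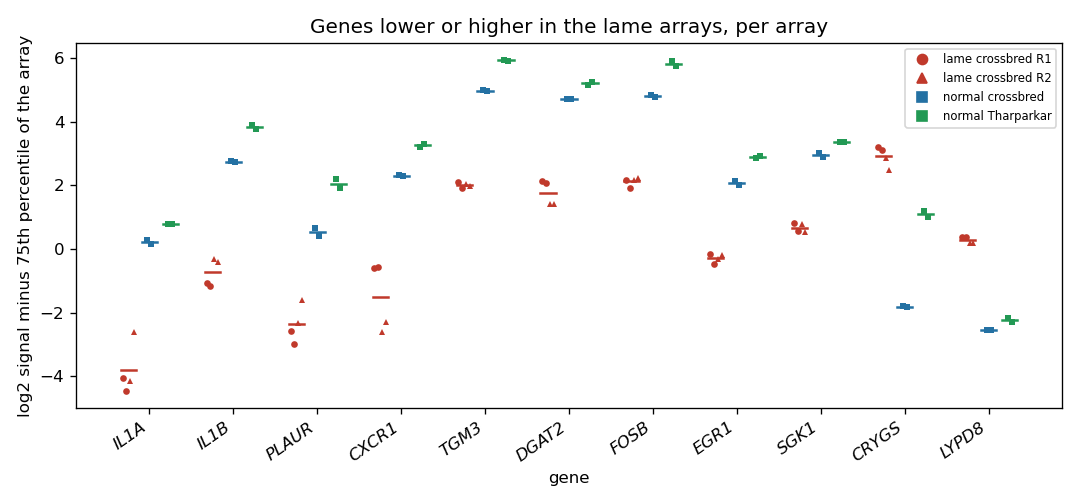
Values of 11 named genes on each of the 8 arrays, as log2 signal minus the array's 75th percentile; points are arrays, short lines are group means, and the 4 lame arrays are drawn by RNA sample (R1, R2). The lame arrays lie below both normal groups for the first 9 genes, with fold changes against normal crossbred between -4.03 for IL1A and -2.29 for SGK1, and above them for CRYGS and LYPD8.

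Some genes were not well above background on any array of 1 group. BOLA-DQA5, an MHC class II DQ alpha gene, was at least 286-fold lower in the lame than in the normal crossbred arrays (adjusted p = 5.6e-05), KRT24 at least 14.6-fold lower and RUFY4 at least 3.78-fold lower. CPXM2 was at least 19.1-fold higher, PNOC, which encodes the precursor of nociceptin, at least 6.77-fold higher and DPYSL5 at least 6.03-fold higher. BOLA-DQA5 was not well above background on any Tharparkar array either. DPYSL5 was lower in the normal crossbred than in the Tharparkar arrays (log2 fold change -5.35). For both genes the normal crossbred RNA sample thus stood apart from the other groups.

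In all, 1455 of 15137 genes passed the test, 499 higher and 956 lower in the lame arrays, 816 of them by at least 2-fold. The excess of lower genes was present with lame R2 alone (2541 higher, 5052 lower) and not with lame R1 alone (2983 and 2883) or array weights (3737 and 3574). The arrays include technical duplicates, so these p-values are too small as tests of cows. With duplicates averaged, 167 passed, but that fit has 1 value per normal group and acts as a minimum on the fold change. After quantile normalization, where its prior is finite, 0 passed in limma (610 at an unadjusted p under 0.05). Simulated groups with no difference, but with the spread seen between lame R1 and lame R2, gave on average 2008 calls (1826 to 2153), and 100 of 100 simulations reached the observed 1455, so the number of calls does not exceed that spread. With slide as a block 1000 genes passed, and with normexp 633 (137 higher and 496 lower). Leaving out a normal crossbred array gave 179 or 186, and leaving out a Tharparkar array 718.

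The comparison of the normal groups addresses breed differences in cows without lameness. S100A13, a calcium-binding protein, was 259-fold higher in the crossbred arrays (8.02, SE 0.42, adjusted p = 0.00013). PRSS2, a trypsinogen, was 32.5-fold higher (5.02, SE 0.17), NUP210, a nuclear pore protein, 23.3-fold higher (4.54, SE 0.45), and COL18A1, a basement membrane collagen, 17.8-fold higher (4.15, SE 0.16), although another of its probes gave -0.11. S100A13, PRSS2 and NUP210 each rest on 1 probe. Whether a sequence difference between the breeds under these probes changed the signal was not tested. DNM1 (3.84, SE 0.35), OSBP2 (3.81, SE 0.36), TSR2 (3.74, SE 0.42) and A2M, a protease inhibitor (3.53, SE 0.40), were also higher. PRSS57, a neutrophil serine protease, was 22.4-fold lower (-4.48, SE 0.59), followed by SERPINB4 (-3.58, SE 0.67), the collagen COL6A1 (-3.53, SE 0.16), ITM2C (-3.47, SE 0.18), PYROXD2 (-3.47, SE 0.51), CFAP96 (-3.40, SE 0.54), TNFAIP6 (-3.26, SE 0.19) and RIN2 (-3.20, SE 0.39).

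T cell, NK and platelet markers were higher in the normal crossbred arrays. Of 31 T cell markers, 18 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.98 (adjusted p = 3.6e-07, and adjusted p = 0.189 with an estimated correlation). IL7R, the receptor of interleukin-7 (1.92, SE 0.20), CD3G, a chain of the T cell receptor complex (1.66, SE 0.29), and FYN, a kinase of T cell signalling (1.56, SE 0.16), were among them. The median was 1.02 within slide 1 and 0.98 within slide 2. Of 21 NK and cytotoxic markers, 10 rose and 1 fell (14 and 1 adjusted over the list alone; median 1.36, adjusted p = 2.6e-05, and adjusted p = 0.485 with an estimated correlation), including CTSW (1.90, SE 0.17), NCR3 (1.53, SE 0.24) and CD244 (1.51, SE 0.20). Of 20 platelet markers, 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.91, adjusted p = 0.000436, and adjusted p = 0.626 with an estimated correlation), including LTBP1 (3.04, SE 0.40), F2R (1.95, SE 0.30) and VWF (1.90, SE 0.24). The gamma-delta T cell median was 1.05 (adjusted p = 0.228), with CD163L1, of the WC1 family (1.74, SE 0.42), higher and ART1 of the same list lower (-1.67).

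Other lists were lower in the normal crossbred than in the Tharparkar arrays. Of 50 cell cycle genes, 11 fell and 0 rose (15 adjusted over the list alone; median -0.56, adjusted p = 2.6e-08, and adjusted p = 0.572 with an estimated correlation), including CCNE1 (-1.95, SE 0.18) and CDCA8 (-1.59, SE 0.27). Of 35 immediate early genes, 9 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.000696, and adjusted p = 0.184 with an estimated correlation). The nuclear receptors NR4A1 (-2.29, SE 0.28) and NR4A2 (-1.74, SE 0.42) fell and the phosphatase gene DUSP10 rose (1.61, SE 0.32). This call was lost with normexp (adjusted p = 0.168). Of 32 glycolysis and hypoxia genes, 7 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.45, adjusted p = 0.0065, and adjusted p = 0.572 with an estimated correlation). The glucose transporter SLC2A1 fell (-1.16, SE 0.29) and PDK1 rose (1.80, SE 0.18). The oxidative phosphorylation list had a median of -0.26 (adjusted p = 0.0035, and adjusted p = 0.671 with an estimated correlation), with 4 of 73 lower and 1 higher, and 0 of either adjusted over the list alone. The ribosomal protein list had a median of -0.16 (adjusted p = 0.0088, and adjusted p = 0.717 with an estimated correlation), with 1 of 75 lower, RPL3, and 0 adjusted over the list alone. Its sign turned with quantile normalization (0.03) and with normexp (0.08). With normexp the oxidative phosphorylation (adjusted p = 0.801) and glycolysis calls (0.34) were lost. The oxidative phosphorylation, ribosomal and glycolysis calls were also lost with duplicates averaged (adjusted p = 0.0796, 0.117 and 0.117) and with fry (0.467, 0.544 and 0.064). The ribosomal call was lost with the mean of a gene's probes as well (0.0713).

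Among the lists that were not called, some MHC class II genes had large differences: BOLA-DYB (-2.17, SE 0.30), BOLA-DOB (-1.89, SE 0.34) and BOLA-DMB (-1.38, SE 0.37) were lower and BOLA-DQA5 was at least 276-fold higher. The MHC class II median was -0.53 and its mean 0.18 (adjusted p = 0.181). Without BOLA-DQA5, which was not well above background in the Tharparkar arrays, the mean was -0.65. The interferon response gene RSAD2 was 2.82-fold higher (list median 0.17, adjusted p = 0.133), and 7 of 30 rose (8 adjusted over the list alone). The B cell genes SPIB (-1.72, SE 0.26) and TNFRSF13C (-1.15, SE 0.24) were lower (list median -0.18, adjusted p = 0.133). Median and mean also differed in sign for plasma cell, erythroid and unfolded protein lists. ACTB (-0.25, SE 0.25), GAPDH (-0.03, SE 0.18) and B2M (-0.10, SE 0.20) did not pass, and the signs of GAPDH and B2M turned with quantile normalization and normexp. PTPRC was higher (0.54, SE 0.15, adjusted p = 0.041).

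BOLA-DQA5 was at least 276-fold higher in the normal crossbred than in the Tharparkar arrays, where it was not well above background. The zinc finger gene ZNF304 was at least 40.5-fold and S100A14 at least 16.7-fold higher. DUSP5, a phosphatase of the ERK pathway, was at least 16.8-fold lower, INHBB at least 10.8-fold and PCDH1 at least 10.5-fold lower.

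**Figure D2:**
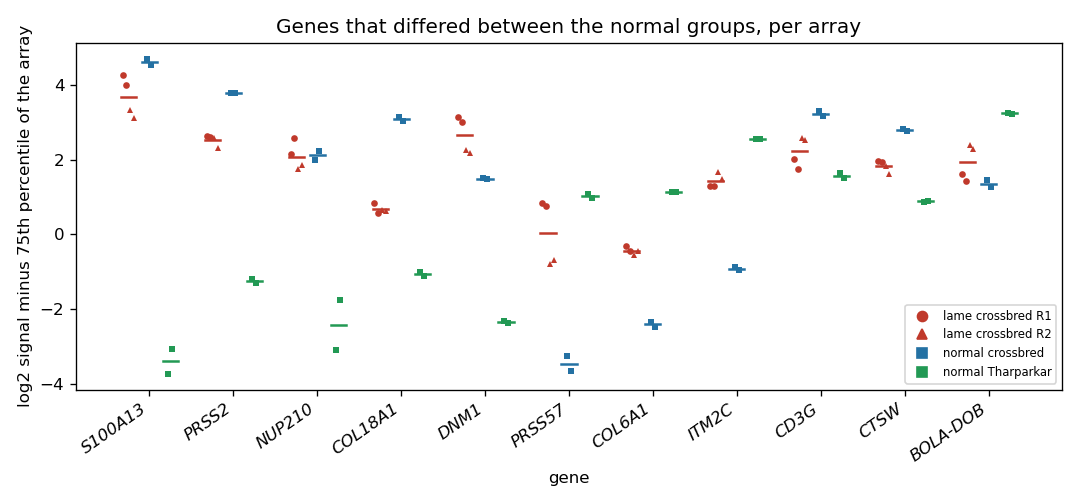
Values of 11 genes that differed between the normal groups on each of the 8 arrays, as log2 signal minus the array's 75th percentile; points are arrays, short lines are group means, and the lame arrays are drawn by RNA sample. Normal crossbred arrays lie above normal Tharparkar arrays for S100A13 by 8.02 on the log2 scale and below them for PRSS57 by a log2 fold change of -4.48.

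In all, 2821 genes passed the test, 1775 higher and 1046 lower in the crossbred arrays, 1841 of them by at least 2-fold. Whether sequence differences between the breeds under the probes contributed to this excess of higher genes was not tested. With duplicates averaged 373 passed in the fit that acts as a minimum on the fold change, and 0 in the quantile-normalized one (863 at an unadjusted p under 0.05). Simulated groups with no difference but the spread between lame R1 and lame R2 gave on average 2014 calls (1872 to 2175), and 0 of 100 reached the observed number. With slide as a block 2274 genes passed, and leaving out normal arrays lowered the count to 714 to 846. Each normal group is 1 RNA sample, so this comparison sets 2 RNA samples against each other, and breed cannot be told apart from the sample.

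The comparison of lame crossbred with normal Tharparkar arrays joins the condition with the breed. CXCR1 was 27.5-fold lower in the lame arrays (-4.78, SE 0.61, adjusted p = 0.0024), the neutrophil-attracting chemokine CXCL2 24.5-fold lower (-4.62, SE 0.16), IL1A 24.2-fold (-4.60, SE 0.48), IL1B 23.8-fold (-4.57, SE 0.27) and PLAUR 21.5-fold lower (-4.42, SE 0.35). TGM3 (-3.91, SE 0.13), CXCL8, which encodes interleukin-8 (-3.84, SE 0.81), and GADD45G (-3.79, SE 0.27) followed. Among genes with a symbol that were well above background on every array of both groups, the highest in the lame arrays were largely those of the breed comparison: S100A13 (7.08, SE 0.36), DNM1, which was 31.9-fold higher (SE of log2 0.30), NUP210 (4.50, SE 0.39), PRSS2 (3.77, SE 0.15), OSBP2 (3.55, SE 0.31), A2M (3.38, SE 0.34) and TSR2 (3.33, SE 0.36). Both comparisons share the Tharparkar arrays, so this overlap can arise from that RNA sample alone. HINFP was higher by 4.19 (SE 0.43) with the probe used and gave -0.38 with another.

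Of 50 cell cycle genes, 35 fell and 0 rose (39 adjusted over the list alone), with a median of -1.19 (adjusted p = 3.95e-17, and adjusted p = 0.358 with an estimated correlation), including CCNE1 (-2.37, SE 0.15), CDCA8 (-2.26, SE 0.24) and BIRC5 (-2.05, SE 0.15). The median was -1.15 within slide 1 and -1.14 within slide 2. Of 35 immediate early genes, 23 fell and 1 rose (25 and 3 adjusted over the list alone), with a median of -1.27 (adjusted p = 1.4e-11), and this call held (adjusted p = 0.0115 with an estimated correlation). FOSB (-3.70, SE 0.15), NR4A2 (-3.65, SE 0.36) and the phosphatase gene DUSP2 (-3.64, SE 0.37) fell. The median was -1.29 within slide 1 and -1.33 within slide 2. Of 28 inflammatory genes, 14 fell and 5 rose, the same counts adjusted over the list alone (median -1.05, adjusted p = 0.0038, and adjusted p = 0.358 with an estimated correlation). Of 20 platelet markers, 12 rose and 2 fell (13 and 3 adjusted over the list alone; median 1.19, adjusted p = 0.000203, and adjusted p = 0.385 with an estimated correlation), including VWF (2.78, SE 0.20) and TUBB1 (2.19, SE 0.43), with medians of 0.79 for lame R1 and 1.44 for lame R2.

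Of 31 T cell markers, 5 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.42, adjusted p = 0.0234, and adjusted p = 0.358 with an estimated correlation). IL7R rose 2.83-fold (SE of log2 0.17) and CD69, an activation marker, fell (-1.27, SE 0.25). The call was lost without lame R2_1 (adjusted p = 0.0752), without lame R2_2 (0.0642) and with duplicates averaged (0.172). Of 13 MHC class II genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.61, adjusted p = 0.0178, and adjusted p = 0.358 with an estimated correlation): BOLA-DYB (-2.42, SE 0.26) and BOLA-DOB (-1.31, SE 0.29) fell and the protease LGMN (1.40, SE 0.17) rose. This call was lost with quantile normalization (adjusted p = 0.288), with normexp (0.451) and with duplicates averaged (0.0637). Of 73 oxidative phosphorylation genes, 7 fell and 1 rose, and 0 of either adjusted over the list alone (median -0.36, adjusted p = 0.0021, and adjusted p = 0.768 with an estimated correlation). Its median was -0.02 for lame R1 and -0.63 for lame R2, and -0.22 without lame R2_2. Of 32 glycolysis and hypoxia genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.22, adjusted p = 0.0234, and adjusted p = 0.385 with an estimated correlation), with medians of -0.15 for lame R1 and -0.54 for lame R2, and the call was lost without lame R2_2 (adjusted p = 0.0642) and with duplicates averaged (0.141). Both of these calls were also lost with quantile normalization and with normexp, and that of oxidative phosphorylation with fry (adjusted p = 0.281).

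Among the lists not called, granulocyte markers had 10 of 30 lower and 4 higher (10 and 5 adjusted over the list alone; median -0.26, -0.36 for lame R1 and 0.12 for lame R2, and -0.44 without lame R2_2, adjusted p = 0.115), including ELANE, neutrophil elastase (-2.21, SE 0.30). Erythroid markers had 7 higher and 2 lower (median 0.28, adjusted p = 0.122), among them ALAS2 (2.21, SE 0.38) and HBB (1.34, SE 0.31). CD14 (-1.62, SE 0.31), TLR4 (-2.48, SE 0.35) and IFIT3 (-3.10, SE 0.30) were lower here as well, although the interferon response list was not called (median -0.23). Median and mean differed in sign for matrix genes (0.29 and -0.37), epithelial markers (0.18 and -0.30), gamma-delta T cell markers (0.21 and -0.05) and pattern recognition receptors (0.01 and -0.07). Without lame R2_2 the median was 0.17 for matrix genes and turned to -0.01 for epithelial markers, -0.27 for gamma-delta T cell markers and -0.16 for pattern recognition receptors. CORO1B was at least 36.9-fold higher, although another of its probes gave a log2 fold change of 1.03, ZNF304 at least 32.5-fold and UNC93A at least 31.1-fold higher in the lame arrays. DUSP5 was at least 12.9-fold, RUFY4 at least 8.80-fold and OSM, a cytokine of the interleukin-6 family, at least 7.81-fold lower.

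In all, 3521 genes passed, 1891 higher and 1630 lower in the lame arrays, 1863 of them by at least 2-fold. With duplicates averaged 531 passed in the fit that acts as a minimum on the fold change, and 0 in the quantile-normalized one (998 at an unadjusted p under 0.05). Simulated groups with no difference but the spread between lame R1 and lame R2 gave on average 2013 calls (1863 to 2198), and 0 of 100 reached the observed number. With slide as a block 2899 genes passed, with normexp 2000 (733 higher and 1267 lower), and leaving out a Tharparkar array gave 852 or 919.

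Some genes differed from both normal groups in the same direction. Among those with a symbol that were well above background on every array of the groups compared, IL1A, CXCR1, IL1B, DGAT2, TGM3 and PLAUR were the lowest, and LYPD8, POP1, CRYGS, PPP1R1B, EHD1 and TAC3, the precursor of neurokinin B, the highest. CXCR1 and TGM3 are members of the granulocyte list. EHD1 rose by 1.73 (SE 0.18) and 2.14 (SE 0.18) against the crossbred and the Tharparkar arrays, although the mean of its probes turned the second value to -0.08. Of 35 immediate early genes 16 were lower in both comparisons, of 28 inflammatory genes 9, of 50 cell cycle genes 7 and of 30 granulocyte markers 7, with 1 higher. In total 549 genes passed in both, 189 higher and 360 lower, and 157 passed in opposite directions. The excess of lower genes was present with lame R2 alone (1439 higher, 3151 lower) and not with lame R1 alone (1377 and 1325) or array weights (1682 and 1604). Independent lists would share 62.3 higher and 103 lower genes. The 2 comparisons share the lame arrays, and unchanged groups simulated with the RNA-sample spread gave 630 such genes on average (555 to 705), with 100 of 100 simulations at or above 549. With array spread alone they gave 0. The covariance of the fold changes was 0.184, against 0.154 on average in those simulations (0.136 to 0.170, with 0 of 100 as large) and 0.0348 with array spread alone. The correlation was 0.307, against 0.333 and 0.332. With duplicates averaged 67 genes passed in both, and 0 after quantile normalization.

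**Figure D3:**
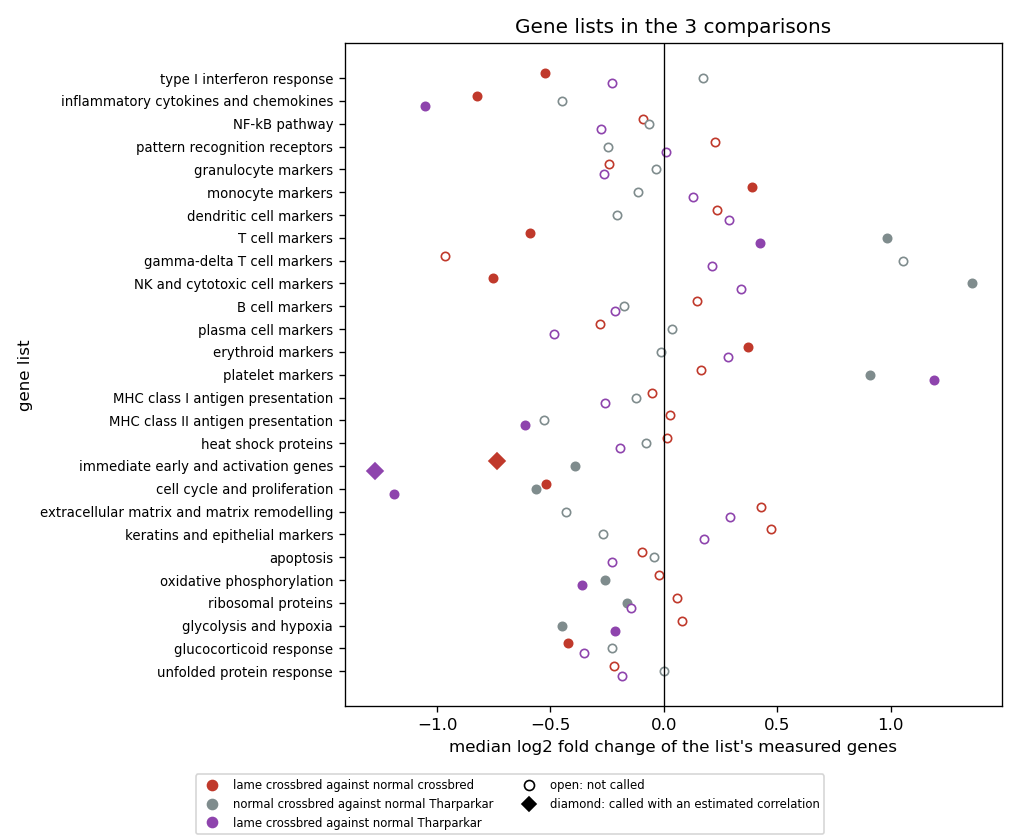
Median log2 fold change of the measured genes of each of the 27 lists in the 3 comparisons; filled points passed camera at the preset correlation, and diamonds also passed with an estimated correlation. The immediate early list lies at -0.74 and -1.27 in the lame arrays against normal crossbred and normal Tharparkar arrays, and these are the 2 diamonds.

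Of the 27 lists, 9, 8 and 8 were called in the comparisons in the order given, and with an estimated correlation 1, 0 and 1, the immediate early list each time. Probes of a gene did not always move together: of called genes with several probes, 115 of 525, 185 of 998 and 322 of 1300 had a probe that pointed the other way.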

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

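Except for the outlier and control spot values, the tests in this part were chosen after the results they address were seen. Lame R2_1 lay far below the other lame arrays in the median level of the immediate early list, at 1.90 against 2.17 to 2.22 on the log2 scale. It also lay far below them in the level of CEBPB, at -3.11 against -2.56 to -2.50. Dixon's ratio was 0.849 for the list and 0.899 for CEBPB, both above the 95% critical value for 4 arrays. With 4 independent arrays, chance marks about 1 in 20 groups in this way. The lame arrays read as 2 RNA samples in duplicate, so that rate need not hold here. In all, 5 array measures, 27 lists and 173 genes were tested, of which these 2 passed. The E1A spots, which detect spike-in transcripts and were used in no comparison, had a median raw signal of 167.25 on lame R2_2 against 55 to 76 on the other arrays. Negative control spots gave 107 on lame R2_2 and 53 to 65 on the others, so E1A spots lay little above background on those. Lame R2_1 had the largest gap among them, 76 against 65.

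The number of genes called in lame against normal crossbred arrays was set against the spread between RNA samples. Simulated groups with that spread and no difference gave at least as many calls as observed, 1455, in 100 of 100 simulations (mean 2008). That spread comes from lame R1 and lame R2 alone, R2 includes the bright array R2_2, and genes were drawn independently. It may not equal the spread between other cows. The count therefore shows only that no more genes were called than the spread of these lame RNA samples gives. With a 2-fold minimum the count was 816, which 84 of 100 simulations reached. Against Tharparkar arrays, 0 of 100 simulations reached the observed counts. That result leaves breed and the spread between normal cows open, since each normal group held 1 RNA sample.

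The immediate early and inflammatory genes that were lower in the lame arrays could reflect the cells in the preparations, the brightness of 1 array, or the condition. Granulocyte markers held in no other list had medians of -0.19 against either normal group with quartiles of -1.70 to 0.43 and -2.21 to 0.47. The whole granulocyte list moved from -0.24 to -0.50 and from -0.26 to -0.44 without lame R2_2. Of its 30 members, 7 were lower against both normal groups, CXCR1, CXCR2 and TGM3 among them, and 1 was higher. The bright markers S100A12 (-0.11 and 0.20) and S100A8 (-0.29 and -0.40) moved little. Fewer granulocytes in the lame preparations thus stay possible. Fewer monocytes would lower the monocyte list, whose median was 0.39 against the normal crossbred and 0.13 against the Tharparkar arrays. Of 29 monocyte markers, 3 were higher against both normal groups and 1, CD14, was lower. The list thus argues against fewer monocytes without excluding them, since the test was chosen after the results were seen. The high background of lame R2_2 does not account for the lower immediate early list, because its median stayed at -0.62 and -1.28 without that array. Activation of the normal cells during handling before RNA isolation was not tested and stays open beside lameness.

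Differences of at least 16-fold were called for 126 pairs of a gene and a comparison, and a sequence variant or a paralog under 1 probe could produce such a value. Only 26 of these pairs had another probe, and of their 37 other probes 30, or 81.1%, moved the same way by at least 25% of the change on the log2 scale (exact 95% interval 64.8% to 92.0%). For genes at 4 to 16-fold the share was 84.4% of 339 probes, so neither reading is settled. The pairs with 1 probe stay untested, and so does a haplotype difference that affects every probe of a gene.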

How the results depend on the processing

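Alternatives marked as added were chosen after seeing the data. For counts of genes, values follow in the order lame against normal crossbred, normal crossbred against Tharparkar, lame against Tharparkar, and both normal groups in the same direction (1455, 2821, 3521 and 549 as reported). Of the alternative counts, 51 stayed within 1.5 times the reported one and 58 did not. Counts were 633, 1311, 2000 and 240 with normexp, 356, 995, 1358 and 146 with no filter on dim probes, and 167, 373, 531 and 67 with duplicates averaged by the first number, where an infinite prior makes a call depend on the fold change alone. With lame arrays alone averaged, the first was 808 and the last 321. Array weights gave 7311, 9453, 8478 and 3286, with lame R2_1 and R2_2 weighted at 0.113 and 0.0797. Fits on the 2 groups compared gave 718, 8714 and 2310. Quantile normalization with duplicates averaged (added) gave 0, 0, 0 and 0 in limma, with 610, 863 and 998 genes at an unadjusted p under 0.05. Lame R1 alone gave 5866, 7304 and 2702 against crossbred, Tharparkar and both, and lame R2 alone 7593, 9172 and 4590 (added). The 4 RNA samples as groups gave 7629 between the normal groups (added). A 2-fold minimum gave 816, 1841, 1863 and 279, and an adjusted p under 0.01 gave 432, 1099, 1417 and 161. Genes called in both lame RNA samples numbered 2724 against crossbred and 1035 against both (added). Leaving out each array gave 179 to 1810, 714 to 3981, 852 to 3910 and 90 to 641; the low ends came from leaving out a normal array, which leaves that group 1 array, assumed to vary like the others. A replicate block by the number after R gave 1747, 3368, 4221 and 682, and by the last number, which is the slide, 1000, 2274, 2899 and 394; deviations of same-numbered arrays correlated at -0.108 to 0.238 for the number after R, which does not pair the arrays, and at 0.0401 to 0.238 for the slide, whose arrays deviated together to that degree. Normexp moved the median of all genes to -0.10 between the normal groups and -0.16 in lame against Tharparkar. It moved the higher and lower calls from 499 and 956 to 137 and 496 in lame against normal crossbred, and from 1891 and 1630 to 733 and 1267 in lame against Tharparkar.

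Of named gene results, 4805 kept direction and call, 1354 lost the call, 35 gained it and 27 changed sign. With slide as a block, 219 of 256 named gene results were kept and 37 lost the call. Of results for the 25 list calls, 337 kept, 60 lost the call and 3 changed sign. With duplicates averaged, 20 of 68, 17 of 81 and 34 of 90 named calls remained, those with the largest fold changes; against normal crossbred, CD8A (adjusted p = 0.757), NKG7 (0.67), C1QB (0.527) and CDK1 (1.00) were among those that lost it. In lame against normal crossbred, the mean of a gene's probes gave BAG1 0.042, ACTB -0.066 and GAPDH 0.031, and lame R2 alone gave RPL39 -0.56 and ACTB -0.11. Between the normal groups, the mean of probes gave RPL3 0.17, quantile normalization, with or without averaging, GAPDH 0.163 and B2M 0.082, normexp GAPDH 0.21 and B2M 0.21, and leaving out each array gave B2M -0.239 to 0.044, the highest without Tharparkar R1. In lame against Tharparkar, the mean of probes gave CD5 0.043, RPL3 0.472 and EHD1 -0.084, and normexp gave XCL1 -0.35, GATA1 -0.029, ACTB 0.20 and GAPDH 0.12. There, quantile normalization, with or without averaging, gave ACTB 0.219 and GAPDH 0.094, array weights ACTB 0.135 and lame R1 alone ACTB 0.169, and leaving out each array gave ACTB -0.190 to 0.029, the highest without lame R2_1. The ribosomal list between the normal groups was 0.034 with quantile normalization, with or without averaging, and 0.077 with normexp. For these sign changes and moved counts the cause was not tested. Genes without a group in which every array was well above background were not tested.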

Other observations

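The 2 lame RNA samples differed from each other in whole groups of genes. These differences were examined after the data were seen, and the neighbour test that follows was stated before its result; its repeat without 1 pair was added after. Of 75 ribosomal protein genes, 74 were higher in lame R1 than in lame R2, with a median log2 difference of 0.60, and of 73 oxidative phosphorylation genes 71 were, with a median of 0.63. Of 50 cell cycle genes 41 were higher in R1 (0.38). Of 20 platelet markers 19 were lower in R1 (-0.65), as were 16 of 21 NK and cytotoxic markers (-0.39) and 15 of 21 pattern recognition receptors (-0.55). By the spread between duplicates, 8453 genes differed between R1 and R2, 5524 higher and 2929 lower in R1, 2021 of them by at least 2-fold. Lame R2 includes the bright array R2_2, whose part in these differences was not separated from that of the RNA sample. Without that array the ribosomal median against normal crossbred moved from 0.06 to 0.17.

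As a hypothesis, large differences between the normal groups might cluster in neighbouring genes, as S100A13 (8.02) and S100A14 (at least 16.7-fold, since it was not well above background in the Tharparkar arrays) do. Among 8926 genes in order, 271 differed by at least 4-fold, and 9 adjacent pairs did so in the same direction, against a median of 4 and a 95th percentile of 8 in 10000 permutations of the genes (permutation p = 0.033, and 0.066 adjusted over 2 tests). That count includes the pair that prompted the test. Without S100A13 and S100A14, 8 pairs remained, no more than the 95th percentile of 8 (permutation p = 0.061), so the hypothesis stays open. Some pairs, such as CXCL2 with CXCL3 and PTPRR with PTPRB, are related genes that a shared sequence could link. Between lame R1 and lame R2 there were 2 such pairs among 130 genes, both at the lysozyme gene LYZ2 and its neighbours, against a permuted median of 1 (permutation p = 0.37), which settles nothing.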
